A study of Mus musculus with 24 samples.

How the data were processed

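Total RNA from mouse aorta was labelled with Cy3 by low-input amplification and hybridised to 24 one-colour Agilent arrays, per the labels' protocols. Those protocols speak of RNA from cells, while the sample labels name the aorta. Each array came with its scanner output, in which the processed signal is a spot intensity on a linear scale, background-subtracted and detrended within the array and not normalised between arrays, per the file headers. The headers name Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name 9.5.1.1. Flags for spots well above background, saturated or outlying were used as deposited. The authors' processed values for the same arrays were used as an alternative. They are deposited as intensity on a linear scale and were quantile-normalised, since every column has the same sorted values (median 30.982), and the lowest Spearman rho of a column with its scanner values was 0.99997. Any step besides stays unknown, and the values show no centring of genes and no turned direction.

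Each array had 59305 spots outside controls, for 55681 probes. Over the 24 arrays 2910 outlier spots were left out, and spots of a probe were averaged. The processed signal was taken as log2 minus the array's 75th percentile, which lay between 270 and 772 before log2 (383 to 772 on knockout and 270 to 460 on wild-type arrays). Spike-in slopes were 0.932 to 0.981 on knockout and 0.884 to 0.908 on wild-type arrays. A probe was kept where it was well above background on all 3 arrays of at least 1 group and had a value on at least 2 arrays of every group, which left 33374 probes. Of all probes, 27235 were named through an accession in a RefSeq table of GRCm38.p6, which was used for names only since the array's coordinates are on mm9. A further 3581 kept a file name that is a RefSeq symbol and 24865 another file name. The brightest probe stood for a gene, which gave 23503 genes, 8673 of them under a database name. Of 6622 genes with several probes, 53 had probes called in both directions for infusion in the wild type and 53 for salt with infusion in the wild type, 55 and 38 for the same comparisons in the knockout, and 189 and 123 for genotype in controls and under salt with infusion. Atp5g1, for infusion in the knockout, was the named gene with such a probe.

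Samples were grouped by the labels. Of the wild-type salt group, titles and source names give different replicate numbers (2 to 4 and 1 to 3), and the source names' were used, so an array's number there, and any pairing by number, is uncertain. One linear model over all 24 arrays, with a mean for each group and a shared spread, gave 10 comparisons between groups and 4 differences of such comparisons between the genotypes (lmFit and eBayes in limma 3.58.1, R 4.3.3). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 36 gene lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The text shortens the lists of macrophages (and monocytes), mesothelial (and epithelial) cells, brown adipocytes (and thermogenesis) and osmotic response (and sodium transport). Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and 38 genes with a missing value were left out there. Files were read with the R package data.table, version 1.17.8, and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

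Il17a and Il17f were always named. In each comparison of 2 groups, the rule named the 10 largest positive and the 10 largest negative log2 changes among genes past the threshold whose 3 arrays of one group all lay above the 3 of the other. For each difference between genotypes it named the 5 largest of each sign past the threshold, and where fewer than 5 passed, the 5 smallest p of each sign. It also named up to 4 members of smallest p of each list that passed, and 4 of the IL-17 response list in each of its 4 planned tests. Genes with only a database name were counted and not named.

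The alternatives were quantile normalisation, normexp background correction with an offset of 50, the authors' processed values, no filter on dim probes, only probes well above background on all 24 arrays, the mean of a gene's probes, a prior variance with a trend, slide as a fixed and as a random block (correlation 0.483), the replicate number as a block, only the compared groups in the fit, the arrays of 1 slide, and each array left out in turn. Leaving out the third infusion-only arrays of both genotypes was added after seeing the data.

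The tests were tried on simulated arrays with 23465 genes, 200 of them changed. For salt in the wild type the share recovered at a log2 change of 0.5, 1, 2 and 3 was 12%, 66%, 92% and 100%, with 7 false calls. For infusion in the wild type it was 16%, 66%, 94% and 100%, with 17 false calls. For salt under infusion in the wild type it was 16%, 56%, 90% and 94%, with 77 false calls. With only the compared groups in the fit it was 0%, 0%, 68% and 94%, with 4 false calls. For the genotype difference of salt with infusion it was 2%, 24%, 84% and 96%, with 11 false calls. A list shifted by 0.5 for salt in the wild type was called (adjusted p = 2.18e-15) and 0 of 35 others were. No correlation between genes was simulated.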

Results

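RNA from the aorta of mice was hybridised to 24 one-colour Agilent arrays, 3 in each of 8 groups that cross genotype, salt and infusion. Mice were wild-type C57BL/6 or IL-17 knockouts on the same background, drank plain water or 1% NaCl, and received for 3 days either vehicle or an infusion of β-aminopropionitrile (BAPN, an inhibitor of the lysyl oxidases that crosslink collagen and elastin) with angiotensin II, a combination used to bring on aortic dissection. The series states that the 3 replicates of a group are biological. Between 51.1% and 60.8% of the spots of an array were well above background, no spot was saturated, and 23503 genes entered the tests. The number of arrays limits the precision of every value.

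The deleted gene was examined first. The probe for Il17a, which encodes the cytokine interleukin 17A (mm9 chromosome 1, 20724404 to 20724463), and the probe for Il17f, its nearest relative, were well above background on 0 of the 24 arrays, wild-type arrays included. Their normalised log2 signals lay between −7.67 and −5.60 for Il17a and between −7.41 and −5.42 for Il17f. The lowest signal of any probe well above background lay between −5.37 and −4.13 on the same arrays. No fold can be given for either gene. The labels name neither the IL-17 gene nor the part of it that was deleted, so these probes check nothing about the genotypes. A list of 12 measured genes of the IL-17 family, its receptors and Th17 cells passed camera, limma's gene set test, in no comparison. Its median log2 change was 0.11 with infusion (adjusted p = 0.966) and −0.01 with salt and infusion (adjusted p = 0.762) in the wild type.

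The arrays came from 4 slides, each scanned in 1 session, and no slide held both genotypes. Of the knockout, slide 1 held controls, the salt group and infusion arrays 1 and 2. Slide 2 held its infusion array 3 and arrays with salt and infusion. Of the wild type, slide 3 held controls, the salt group and arrays 1 and 2 with salt and infusion. Slide 4 held its infusion group and array 3 with salt and infusion. Salt alone was therefore compared within a slide in both genotypes. Infusion in the wild type and salt with infusion in the knockout were compared across slides. A slide term there rests on the arrays of the group that lay on both. Where groups shared a slide, slide as a block and the fit within that slide compare nearly the same arrays. The pair is not separate support. For salt under infusion they rest on 1 array with salt (array 3) against 3 without in the wild type, and on 3 with salt against 1 without (array 3) in the knockout.

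In the wild type, infused mice on plain water were compared with vehicle controls, 3 arrays against 3. The infusion changed 6086 genes, 2864 upward and 3222 downward (limma, adjusted p under 0.05). Il6, an acute inflammatory cytokine, rose at least 41.8-fold (adjusted p = 0.00369; well above background on 2 of 3 infused and 0 of 3 control arrays). Spp1, the matrix protein osteopontin, rose at least 63.9-fold (adjusted p = 0.000139), and Ccl2, which draws in monocytes, rose 21.9-fold (log2 4.45, SE 0.63, adjusted p = 0.000157). Inmt, which methylates indole amines, fell 21.0-fold (log2 −4.39, SE 0.56, adjusted p = 8.81e-05).

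A bound such as that for Il6 was used where a gene was not well above background on any array of a group. The mean of the brighter group over all 3 arrays was set against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

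The inflammatory cytokine and chemokine list had a median log2 change of 2.42 after infusion in the wild type, with 18 of 25 measured genes higher and 1 lower (22 and 1 when adjusted over the list alone). The list of IL-17 response genes, transcripts that cells make when IL-17 acts on them, had a median of 1.52, with 11 of 23 higher and 0 lower (16 and 1 adjusted over the list alone). Camera gave adjusted p = 6.7e-10 and 4.89e-06 for the pair, and adjusted p = 0.216 and 0.373 with an estimated correlation between genes. With the dim genes at their bound the IL-17 response median was 0.85. Lcn2, an iron-scavenging protein that IL-17 induces in many cells, rose 5.83-fold (log2 2.54, SE 0.59, adjusted p = 0.00478), and 1.65 on the log2 scale without wild-type infusion array 2.

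Macrophage markers rose in the same comparison, 22 of 26 higher and 0 lower (22 and 1 adjusted over the list alone), among them the scavenger receptor Msr1, 6.23-fold, and the lysosomal marker Cd68, 2.99-fold. Neutrophil markers had a median of 2.31 over 18 genes, or 1.37 with dim genes at their bound, with 8 higher and 0 lower (13 and 1 adjusted over the list alone), and a median of 1.24 without wild-type infusion array 2. For these 2 marker lists camera gave adjusted p = 4.23e-08 and 0.000309, and adjusted p = 0.373 for both with an estimated correlation. Cell cycle genes had the largest median of the 36 lists, 3.65, with 29 of 31 higher and 0 lower (30 and 0 adjusted over the list alone; camera adjusted p = 1.43e-25; adjusted p = 0.216 with an estimated correlation). Prc1, which bundles spindle microtubules at division, rose 19.5-fold, Cdca8, a part of the chromosomal passenger complex, 15.4-fold, and Cdk1, the kinase that starts mitosis, at least 31.6-fold (adjusted p = 6.23e-05). The kinetochore protein Ska3 rose at least 7.12-fold.

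Genes of collagens and fibrillar matrix rose in the infused wild type, with 16 of 30 higher and 1 lower (17 and 1 adjusted over the list alone; median 0.58; camera adjusted p = 1.88e-06; adjusted p = 0.0675 with an estimated correlation). Col8a1, a short-chain collagen of the vessel wall, rose 14.5-fold (log2 3.86, SE 0.51, adjusted p = 0.000104) and Col12a1 6.18-fold. Elastic fibre and crosslinking genes had a median of 0.39, with 8 of 24 higher and 2 lower (11 and 2 adjusted over the list alone), and 0.25 and 0.26 without wild-type infusion arrays 1 and 2. Lox, a lysyl oxidase that BAPN inhibits, rose 3.87-fold (log2 1.95, SE 0.31, adjusted p = 0.000389). Among 28 matrix proteases and inhibitors 11 were higher and 2 lower (12 and 3 adjusted over the list alone), including Timp1, an inhibitor of metalloproteinases, 14.1-fold and Mmp19 3.95-fold. For elastic fibre genes and proteases camera gave adjusted p = 0.00144 and 0.000999, and adjusted p = 0.216 for both with an estimated correlation. Cartilage and bone genes had a median of 1.23, 5 of 11 higher and 0 lower under either adjustment, and a median of 0.81 without wild-type control array 3 (camera adjusted p = 0.0675 with an estimated correlation).

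Contractile smooth muscle genes fell, with a median of −0.54, 0 of 23 higher and 8 lower (0 and 9 adjusted over the list alone; camera adjusted p = 0.000161; adjusted p = 0.543 with an estimated correlation). Synpo2, an actin-bundling protein, fell 4.12-fold (log2 −2.04, SE 0.39, adjusted p = 0.00124), and the tropomyosin Tpm1 changed by −0.93. Fibroblast markers had a median of −0.34 with 0 of 19 higher and 8 lower under either adjustment (camera adjusted p = 0.00973; adjusted p = 0.543 with an estimated correlation). That median was −0.52 without wild-type control array 1, −0.21 without wild-type control array 2 and −0.36 without wild-type control array 3, where camera gave adjusted p = 0.088. The ferritin receptor Scara5 fell 5.24-fold. The white adipocyte list had a median of −0.61 with 0 of 19 higher and 4 lower under either adjustment (camera adjusted p = 0.00752; adjusted p = 0.543 with an estimated correlation; adjusted p = 0.0988 without wild-type control array 3).

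In this comparison 261 genes passed with slide as a block, 171 higher and 90 lower, and 770 with slide as a random block. Of the 20 genes with the largest changes 20 then had the same direction and 6 passed, among them Cdk1, Ska3 and Inmt, while Il6 (adjusted p = 0.492), Spp1 (adjusted p = 0.0828) and Ccl2 (log2 3.37, adjusted p = 0.163) did not. Of the 14 lists that passed 11 still did with the slide block, where the medians were 1.65 for inflammatory genes, 0.93 for IL-17 response genes (adjusted p = 0.000877) and 2.88 for cell cycle genes, against −0.16 for contractile genes (adjusted p = 0.136), −0.29 for fibroblast markers (adjusted p = 0.462) and 0.04 for white adipocyte markers (adjusted p = 0.896). The count was 3760 without wild-type control array 1, 2674 without wild-type infusion array 2, 1237 with only the compared groups in the fit and 9405 without the third infusion-only arrays of both genotypes.

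**Figure D1:**
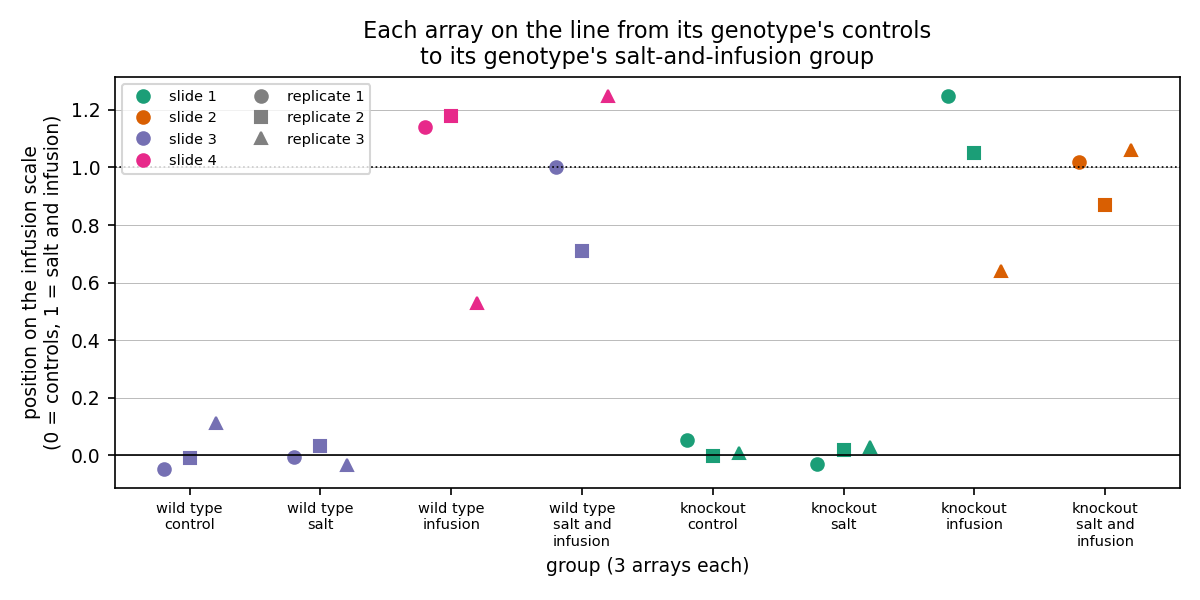
Position of each of the 24 arrays on a scale where 0 is the mean of its own genotype's controls and 1 the mean of its own genotype's arrays with salt and infusion, over 2471 genes in the wild type and 2476 in the knockout; points are arrays. Wild-type infusion array 3 lies at 0.531, between the uninfused wild-type arrays, which reach 0.114, and the other infused ones, which start at 0.711. On the knockout scale infusion array 3 lies at 0.642 and arrays 1 and 2 at 1.25 and 1.05.

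Salt and infusion together were compared with vehicle controls on plain water in the wild type, as the exposure under which the study looked for worse dissection. The combination changed 6748 genes, 3119 upward and 3629 downward (limma, adjusted p under 0.05). Il6 rose at least 76.5-fold (adjusted p = 0.00154) and Ccl2 25.3-fold (log2 4.66, SE 0.63, adjusted p = 0.0001). Thbs1, which encodes the matrix glycoprotein thrombospondin 1, rose 16.2-fold (log2 4.02, SE 0.49, adjusted p = 5.52e-05). Esm1, a proteoglycan secreted by endothelial cells, rose 38.5-fold (log2 5.27, SE 0.48, adjusted p = 1.17e-05). Inmt fell 28.7-fold (log2 −4.84, SE 0.56, adjusted p = 4.57e-05).

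The IL-17 response list had a median of 1.04 with salt and infusion in the wild type, 0.76 with dim genes at their bound, and 8 of 23 genes were higher and 1 lower (9 and 2 adjusted over the list alone). Its camera adjusted p was 0.00042, and adjusted p = 0.478 with an estimated correlation. The median was 1.15 both with slide as a block (adjusted p = 0.00111) and within slide 3 (adjusted p = 3.73e-05). Inflammatory genes had a median of 2.05, with 17 of 25 higher and 1 lower (18 and 1 adjusted over the list alone), and of 1.98 with the slide block and within slide 3. Cell cycle genes had a median of 3.62, with 29 of 31 higher and 0 lower under either adjustment, and of 3.29 with the slide block. Adjusted p for these 2 lists was 3.38e-08 and 3.55e-25 with camera, and adjusted p = 0.299 and 0.232 with an estimated correlation.

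Macrophage markers again passed, with 16 of 26 higher and 1 lower (19 and 1 adjusted over the list alone), Lgals3 among them at 5.27-fold. Interferon response genes had a median of 0.59, 8 of 26 higher and 0 lower under either adjustment. Cxcl10, a T cell attractant, rose 13.3-fold (log2 3.73, SE 0.90). The interferon median was 0.39 without wild-type control array 1 and 0.34 (adjusted p = 0.108) without array 2 of the wild type with salt and infusion, and 0.76 with the slide block and within slide 3. Camera gave adjusted p = 1.93e-06 for macrophage and 0.00231 for interferon genes, and adjusted p = 0.452 and 0.535 with an estimated correlation. Of 30 genes of collagens and fibrillar matrix 17 were higher and 2 lower under either adjustment (camera adjusted p = 2.73e-06; adjusted p = 0.0938 with an estimated correlation). Eln, which encodes elastin, rose 2.61-fold (log2 1.39, SE 0.23, adjusted p = 0.000414). Unfolded protein response genes, which raise folding capacity in the endoplasmic reticulum, had a median of 0.56 with 13 of 22 higher and 0 lower under either adjustment, and of 0.47 with the slide block (camera adjusted p = 3.39e-05; adjusted p = 0.452 with an estimated correlation). Hspa5, its main chaperone, rose by 1.03 on the log2 scale (SE 0.19).

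Fibroblast markers fell, 1 of 19 higher and 8 lower (2 and 10 adjusted over the list alone), with Scara5 5.53-fold lower, and camera gave adjusted p = 0.0101, or 0.0566 without wild-type control array 3 (adjusted p = 0.497 with an estimated correlation). White adipocyte markers had a median of −0.93 with 0 of 19 higher and 8 lower (0 and 12 adjusted over the list alone; camera adjusted p = 0.00291; adjusted p = 0.497 with an estimated correlation). Thymocyte markers had a median of −1.44 with 0 of 12 higher and 3 lower (0 and 5 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation), and their camera adjusted p of 0.0221 became 0.0769 with the slide block, 0.219 with a median of −0.89 without wild-type control array 3, and 0.0527 and 0.0717 without arrays 2 and 3 with salt and infusion. Of the 19 lists that passed 16 still did with slide as a block. The 20 genes with the largest changes had the same direction with that block and 18 of them passed. In total 5320 genes passed with the slide block, 6119 within slide 3, and 3917 without array 3 of the wild type with salt and infusion.

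In the knockout, the infusion was compared with vehicle controls. It changed 7202 genes, 3353 upward and 3849 downward (limma, adjusted p under 0.05). Il6 rose at least 72.6-fold (adjusted p = 0.00226), Spp1 at least 44.7-fold (adjusted p = 0.000173) and Ccl2 34.3-fold (log2 5.10, SE 0.63, adjusted p = 4.81e-05). Cthrc1, a secreted protein of injured arteries, rose 27.1-fold (log2 4.76, SE 0.78, adjusted p = 0.000377). Inmt fell 12.7-fold (log2 −3.67, SE 0.56, adjusted p = 0.000225).

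The IL-17 response list had a median of 0.87 after infusion in the knockout, with 8 of 23 higher and 1 lower (9 and 1 adjusted over the list alone), and of 1.13 with slide as a block and within slide 1. Inflammatory genes had a median of 2.22 with 15 of 25 higher and 1 lower (20 and 1 adjusted over the list alone). Camera gave adjusted p = 0.000397 and 1.49e-08, and adjusted p = 0.484 and 0.325 with an estimated correlation. Ccl7, another monocyte attractant, rose 22.1-fold. Interferon response genes had a median of 1.25 with 16 of 26 higher and 0 lower under either adjustment, and of 1.46 with the slide block (camera adjusted p = 1.55e-06; adjusted p = 0.484 with an estimated correlation). Isg15, a ubiquitin-like protein that interferon induces, rose 5.31-fold (log2 2.41, SE 0.38, adjusted p = 0.000277), and Oasl1 6.31-fold. Of 31 cell cycle genes 30 were higher and 0 lower under either adjustment (median 3.75; camera adjusted p = 2.37e-25; adjusted p = 0.286 with an estimated correlation), with the mitotic kinesin Kif20a higher by 4.58 on the log2 scale.

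Macrophage markers rose in the infused knockout, 18 of 26 higher and 1 lower (19 and 1 adjusted over the list alone; camera adjusted p = 2.93e-07; adjusted p = 0.484 with an estimated correlation), Cd68 by 3.98-fold. Collagens and fibrillar matrix genes had 13 of 30 higher and 1 lower (15 and 2 adjusted over the list alone; camera adjusted p = 0.000417; adjusted p = 0.248 with an estimated correlation), with Col12a1 3.80-fold higher. Cartilage and bone genes had a median of 1.13 with 8 of 11 higher and 0 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.129 with an estimated correlation). Contractile genes had a median of −0.46 with 0 of 23 higher and 7 lower under either adjustment, −0.24 without knockout infusion array 2 and −0.81 without knockout infusion array 3 (camera adjusted p = 0.00231; adjusted p = 0.587 with an estimated correlation). Thymocyte markers had a median of −1.41 with 0 of 12 higher and 4 lower (0 and 7 adjusted over the list alone), and their camera adjusted p was 0.00939, or 0.0913 with a median of −0.81 without knockout control array 1 (adjusted p = 0.518 with an estimated correlation). White adipocyte markers had 0 of 19 higher and 7 lower under either adjustment, and their median was −0.54, or −0.94 without knockout control array 3 (adjusted p = 0.505 with an estimated correlation). Mmp9, a gelatinase, fell at least 3.05-fold (adjusted p = 0.000468). With slide as a block 10070 genes passed and 9013 with a random block, 10178 passed within slide 1, and the 20 genes with the largest changes and the 17 lists still passed with the block. The count was 3964 without knockout infusion array 1 and 2390 with only the compared groups in the fit.

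Salt and infusion together changed 6034 genes in the knockout, 2981 upward and 3053 downward (limma, adjusted p under 0.05). Il6 rose at least 66.2-fold (adjusted p = 0.00311), Spp1 at least 59.4-fold (adjusted p = 9.36e-05), and Ccl2 25.7-fold (log2 4.68, SE 0.63, adjusted p = 6.9e-05). Cthrc1 rose 35.7-fold (log2 5.16, SE 0.78, adjusted p = 0.000209) and Kif20a 35.0-fold (log2 5.13, SE 0.57, adjusted p = 1.78e-05). Inmt fell 15.6-fold (log2 −3.96, SE 0.56, adjusted p = 0.000113), and Mmp9 at least 4.37-fold. Under normexp background correction the split was 3013 higher and 4646 lower, and the median change of all genes was −0.113 against −0.0192.

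In the knockout with salt and infusion the IL-17 response list had a median of 0.50, with 7 of 23 higher and 1 lower under either adjustment (camera adjusted p = 0.00742; adjusted p = 0.496 with an estimated correlation), and of 1.58 with slide as a block (adjusted p = 0.024). Inflammatory genes had a median of 2.07 and 14 of 25 were higher and 1 lower (17 and 1 adjusted over the list alone), and interferon response genes had a median of 1.36 and 17 of 26 were higher and 0 lower (18 and 0 adjusted over the list alone). For these lists camera gave adjusted p = 5.13e-08 and 1.56e-07, and adjusted p = 0.373 and 0.496 with an estimated correlation. With the slide block their medians were 3.16 and 1.94. Ccr2, the receptor for Ccl2, rose 9.11-fold. All 31 cell cycle genes were higher under either adjustment (median 4.04, or 6.39 with the slide block; camera adjusted p = 5.43e-29; adjusted p = 0.172 with an estimated correlation). Of 26 macrophage markers 16 were higher and 1 lower (18 and 1 adjusted over the list alone; median 0.99, or 2.31 with the slide block; camera adjusted p = 5.92e-07; adjusted p = 0.496 with an estimated correlation).

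Cartilage and bone genes, 6 of 11 higher and 0 lower (8 and 0 adjusted over the list alone), passed with an estimated correlation as well in the knockout with salt and infusion (camera adjusted p = 0.000169; adjusted p = 0.0413 with an estimated correlation). Acan, the proteoglycan aggrecan, rose 3.27-fold (log2 1.71, SE 0.25). Collagens and fibrillar matrix genes had 13 of 30 higher and 2 lower (16 and 2 adjusted over the list alone; median 0.46, or 0.12 with the slide block; camera adjusted p = 0.000214; adjusted p = 0.172 with an estimated correlation). Contractile genes had a median of −0.29, or −1.40 with the slide block, with 0 of 23 higher and 8 lower (0 and 9 adjusted over the list alone; camera adjusted p = 0.00296; adjusted p = 0.575 with an estimated correlation). Thymocyte markers had a median of −1.97, −1.30 without knockout control array 1 and −3.26 with the slide block, with 0 of 12 higher and 7 lower (0 and 9 adjusted over the list alone; camera adjusted p = 0.000662; adjusted p = 0.496 with an estimated correlation). Fibroblast markers had 1 of 19 higher and 7 lower (1 and 10 adjusted over the list alone), and their camera adjusted p of 0.00404 became 0.173 with the slide block (adjusted p = 0.496 with an estimated correlation). With slide as a block 8167 genes and 12 of the 17 lists passed, and 19 of the 20 genes with the largest changes. The count was 3849 without array 3 of the knockout with salt and infusion. All values with the slide block in this comparison are limited by knockout infusion array 3, as above.

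**Figure D2:**
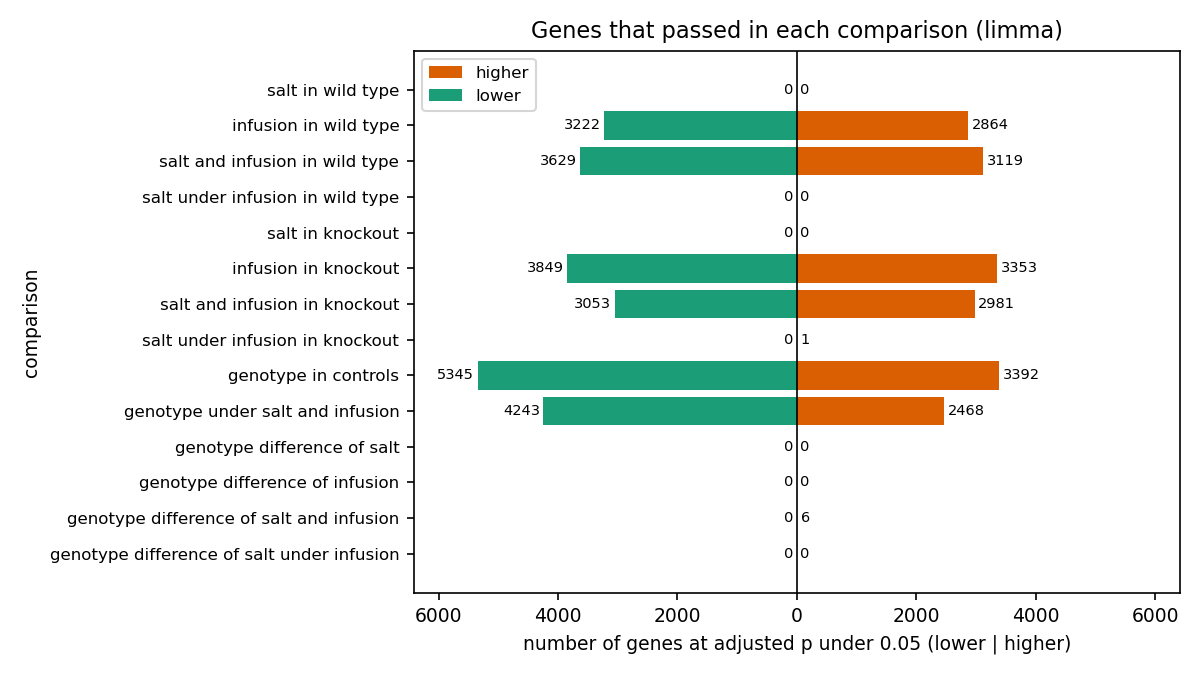
Number of genes higher and lower at limma adjusted p under 0.05 in each comparison; bars are counts. The 4 comparisons with infusion against vehicle have 6034 to 7202 genes, and the 4 comparisons with salt have 0, 0, 0 and 1.

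**Figure D3:**
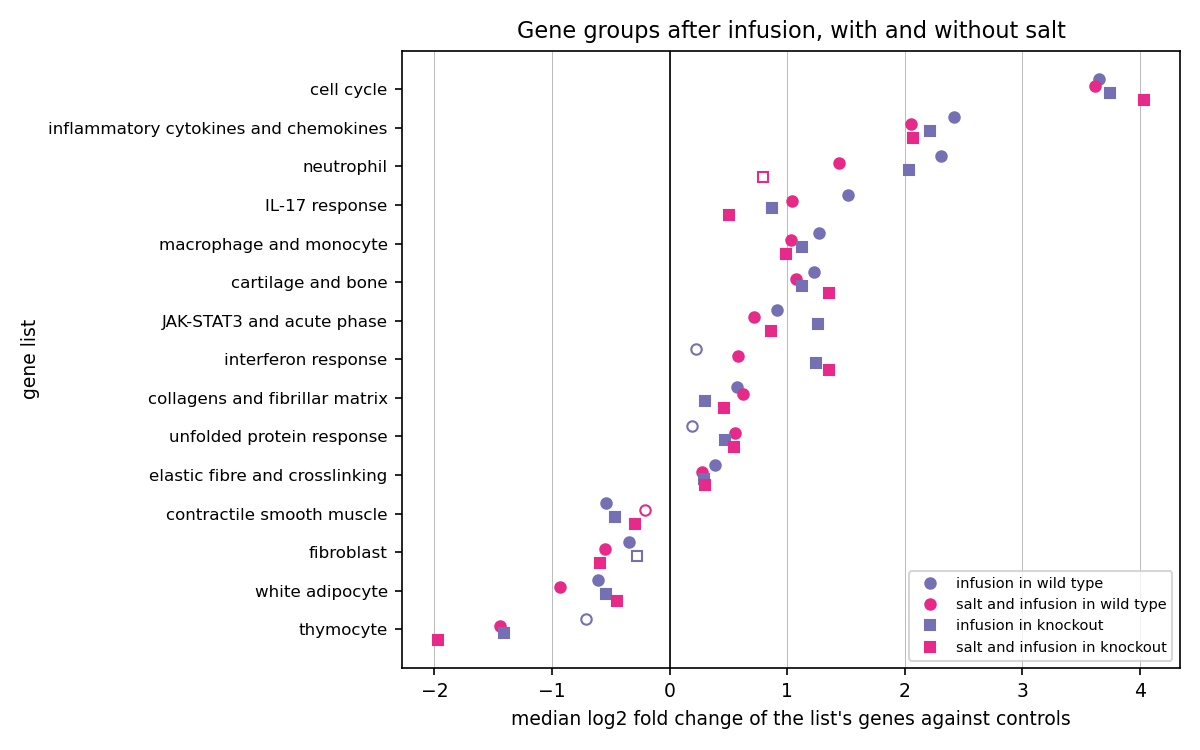
Median log2 change of the listed gene groups in each comparison, with filled points where camera gave an adjusted p under 0.05 and open points elsewhere. Cell cycle genes lie at 3.65, 3.62, 3.75 and 4.04 in the 4 comparisons with infusion against vehicle.

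Whether the response to infusion depended on genotype was tested as a difference of differences. The infusion changed 1962 genes upward in both genotypes, where independent lists of these lengths would share 409, and 2262 downward in both, where 528 would be shared. Only 3 genes passed in opposite directions, and the log2 changes had Pearson's r of 0.815 across genes, which are not independent replicates. The difference itself passed for 0 genes (limma, smallest adjusted p 0.216; 1532 genes at an unadjusted p under 0.05), with 46 under the slide block, 63 without knockout infusion array 3, 15 without wild-type infusion array 3 and 1 without knockout control array 3. For salt with infusion 2086 genes rose in both genotypes against 396 by chance, 2031 fell in both against 471, and r was 0.824 across genes.

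The difference between genotypes in the response to salt with infusion passed for 6 genes (1428 at an unadjusted p under 0.05). Stard3, which tethers late endosomes to the endoplasmic reticulum and moves cholesterol, changed by 0.42 in the knockout and −0.70 in the wild type, a difference of 1.13 (SE 0.16, limma adjusted p = 0.0173). That p was 0.0545 without array 1 of the knockout with salt and infusion, 0.0664 and 0.0579 without wild-type control arrays 1 and 3, and 0.0573 without array 2 of the wild type with salt and infusion. The predicted gene Gm9706 changed by 2.53 in the knockout and 0.23 in the wild type, a difference of 2.30 (SE 0.36, adjusted p = 0.021). Vmn1r139, a vomeronasal receptor gene well above background on 5 of 24 arrays and past the threshold in 1 of the 12 fits that leave out an array (adjusted p = 0.0577 to 0.154 in the others; −0.0671 with normexp background), and 3 transcripts known only by a database name, chosen here after their values were seen, made up the 6. The count was 10 without knockout control array 1 or without array 3 of the wild type with salt and infusion. It was 1 without knockout control array 2, without array 1 of the knockout with salt and infusion or without array 2 of the wild type with salt and infusion, and 0 without wild-type control array 1 or 3. The slide block, limited as in the knockout, gave 1380 genes. A random slide block or quantile normalisation gave 12, and only the compared groups in the fit 24.

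Interferon response genes had the smallest p of the 6 lists whose response to infusion differed between the genotypes, with a median difference of 0.81 (1.25 in the knockout and 0.23 in the wild type; camera adjusted p = 1.96e-07; adjusted p = 0.925 with an estimated correlation). No gene passed alone. With slide as a block the median was 0.40 (adjusted p = 0.338), and it was 0.50 without wild-type infusion array 3. For salt with infusion the list differed by 0.62 (1.36 and 0.59; camera adjusted p = 0.000383; adjusted p = 0.682 with an estimated correlation), by 1.04 with the slide block (adjusted p = 3.45e-05), and by 0.45 without array 3 of the wild type with salt and infusion (adjusted p = 0.086). Differences for the IL-17 response list were −0.23 for infusion (adjusted p = 0.446) and −0.13 for salt with infusion (adjusted p = 0.111), neither past the threshold. The latter was −0.06 with the slide block, 0.02 with slide as a random block, past the threshold with only the compared groups in the fit (adjusted p = 0.0314), −0.36 without array 2 and 0.06 without array 3 of the wild type with salt and infusion.

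Salt without infusion was compared with plain water. In the wild type 0 genes passed (limma, smallest adjusted p 0.0883; 499 at an unadjusted p under 0.05), and in the knockout 0 (714 at an unadjusted p under 0.05). All arrays of each comparison lay on 1 slide. Leaving out 1 array gave at most 1 gene in the wild type, without control array 1 or 2 or salt array 2, and 2 and 1 genes in the knockout without salt arrays 1 and 2. The genes of smallest p in the wild type included Mthfd1l, a mitochondrial folate enzyme, at 1.11 (SE 0.19, adjusted p = 0.139), and in the knockout Cox7a1, a subunit of cytochrome c oxidase, at −0.93 (SE 0.20), and Angptl4, an inhibitor of lipoprotein lipase, at 1.72 (SE 0.45).

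Platelet markers rose with salt in the wild type, by a median of 0.63 over 12 genes (camera adjusted p = 4.29e-06; adjusted p = 0.192 with an estimated correlation), with 0 higher and 0 lower over all genes and 5 and 0 adjusted over the list alone. Gp9, part of the platelet receptor for von Willebrand factor, had log2 2.22 (SE 0.68) and the platelet chemokine Ppbp 2.90 (SE 0.97). The adjusted p was 0.000255 with the slide block, and within slide 3 it was 0.00204. In the knockout the platelet list had a median of 0.38 (camera adjusted p = 0.0108; adjusted p = 0.428 with an estimated correlation), 0.29 without control array 3 (adjusted p = 0.0563) and 0.11 without salt array 2 (adjusted p = 0.397). The difference between genotypes did not pass for this list. Erythroid and B and plasma cell lists passed with salt in the wild type too, each in 2 of 6 fits that leave out an array and with no member past either adjustment. Erythroid markers had a median of 0.94 over 13 genes (camera adjusted p = 0.049, or 0.0182 within slide 3; adjusted p = 0.988 with an estimated correlation), 0.0536 without control array 2 (adjusted p = 0.785) and 1.69 without control array 3. Their adjusted p was 0.105 without control array 1, and 0.375 and 0.0759 without salt arrays 2 and 3. B and plasma cell markers had a median of 0.23 over 12 genes (camera adjusted p = 0.0464, or 0.0724 with the slide block and 0.0239 within slide 3; adjusted p = 0.587 with an estimated correlation). It was 0.11 without control array 2 and 0.14 without salt array 1 (adjusted p = 0.147 and 0.362), and did not pass without control array 1 or salt array 3 (adjusted p = 0.113 and 0.0759). Oxidative phosphorylation genes had a median of −0.10 in the wild type with 0 of 35 past either adjustment (camera adjusted p = 0.000305; adjusted p = 0.988 with an estimated correlation), −0.18 without control array 1 and −0.08 without control array 3 (adjusted p = 0.0592).

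T and NK cell markers fell with salt in the knockout, by a median of −0.80 over 20 genes, −0.66 with dim genes at their bound, and thymocyte markers by −0.97 over 12 genes. No member passed alone. These lists had camera adjusted p = 1.46e-10 and 1.19e-08, and adjusted p = 0.274 for both with an estimated correlation. Lck, a kinase of T cell receptor signalling, had log2 −2.04 (SE 0.68) and Tcf7, a T cell transcription factor, −2.10. Without knockout control array 1 both medians were −0.49 (adjusted p = 0.000105 and 0.0023). The change differed from that in the wild type by −0.74 for T and NK cell markers and −1.04 for thymocyte markers (camera adjusted p = 9.85e-06 for both; adjusted p = 0.854 and 0.751 with an estimated correlation). Without knockout control array 1 these differences were −0.42 and −0.56, and without wild-type control array 2 they were −0.28 and −0.76. The adjusted p was then 0.0595, 0.0595, 0.154 and 0.0595 in that order. Without wild-type control array 3 the T and NK cell difference was −1.28. The IL-17 response list changed with salt by 0.11 in the wild type (adjusted p = 0.426) and −0.04 in the knockout (adjusted p = 0.967), neither past the threshold. Fat markers fell with salt in the knockout, brown adipocyte genes by a median of −0.19 (camera adjusted p = 0.00118; adjusted p = 0.428 with an estimated correlation), with 0 higher and 2 lower adjusted over the list alone, and white adipocyte genes by −0.21 (camera adjusted p = 0.0421; adjusted p = 0.884 with an estimated correlation). The white adipocyte median was −0.0617 without control array 2 and −0.14 without salt array 1 (adjusted p = 0.581 and 0.142), and its adjusted p was 0.0619 without salt array 2.

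Salt during infusion was the comparison closest to the title of the series, high salt making dissection worse through IL-17. Wild-type mice infused on salt were compared with those infused on plain water, and 0 genes passed (limma, smallest adjusted p 0.0722; 1354 at an unadjusted p under 0.05). With slide as a block 9 passed, within slide 4 0 did, 16 passed without array 3 of the wild type with salt and infusion, and 1 without array 2 of that group. The IL-17 response list had a median of −0.20 (camera adjusted p = 0.176; adjusted p = 0.909 with an estimated correlation), with 0 genes higher and 0 lower. Among its genes of smallest p, Cxcl5, a neutrophil attractant, had log2 −1.77 (SE 0.66), Lcn2 −1.04 and the metalloreductase Steap4 −0.59. The median was 0.09 with slide as a block (adjusted p = 0.865), 0.11 without wild-type infusion array 2, and −0.77 without wild-type infusion array 3, where it passed (adjusted p = 8.3e-12). It also passed under normexp correction (median −0.14, adjusted p = 0.0177) and with no filter on dim probes (median −0.22, adjusted p = 0.0245).

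Unfolded protein response genes rose with salt under infusion in the wild type, by a median of 0.32 over 22 genes, 0.53 with slide as a block (adjusted p = 7.99e-09) and 0.16 without wild-type infusion array 3. No member passed alone, with Hspa5 at 0.46 (SE 0.19) and the stress transcription factor Atf4 at 0.42. Oxidative phosphorylation genes rose by 0.12, with 0.34 under the slide block. That median was 0.03 without wild-type infusion array 3 (adjusted p = 0.243) or without array 3 of the wild type with salt and infusion (adjusted p = 0.126), 0.24 without wild-type infusion array 1 and 0.22 without array 2 of the wild type with salt and infusion. Contractile genes rose by 0.28. Their median was 0.02 with the slide block (adjusted p = 0.724), 0.15 without wild-type infusion array 2 and 0.09 without array 2 of the wild type with salt and infusion (adjusted p = 0.119). Camera gave adjusted p = 3.87e-08, 8.56e-06 and 1.33e-05 for the unfolded protein, oxidative phosphorylation and contractile lists, and adjusted p = 0.909 for each with an estimated correlation.

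Neutrophil markers fell with salt under infusion in the wild type, by a median of −0.45 over 18 genes, and immediate early genes, which cells switch on within minutes of a stimulus, rose by 0.28 over 22, with no member past either adjustment. Camera adjusted p was 0.0128 and 0.0017, and adjusted p = 0.909 for both with an estimated correlation. The neutrophil median was −0.28 with the slide block (adjusted p = 0.391), −1.58 without wild-type infusion array 3, −0.74 without array 3 of the wild type with salt and infusion and 0.00846 without wild-type infusion array 2 (adjusted p = 0.944). It was −0.30 without wild-type infusion array 1 (adjusted p = 0.179) or without array 2 of the wild type with salt and infusion (adjusted p = 0.17). The immediate early median was 0.91 with the slide block, which rests on array 3 of the wild type with salt and infusion alone, 0.47 without wild-type infusion array 2, and 0.13 without wild-type infusion array 3 (adjusted p = 0.119). Without arrays 1, 2 and 3 of the wild type with salt and infusion it was 0.42, 0.58 and −0.0463, the last with adjusted p = 0.942. Of the 9 lists that passed 5 still did with the slide block, and 2 turned, interferon response (−0.17) and mesothelial markers (−0.10).

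In the knockout, salt under infusion changed 1 gene. Scube1, a secreted protein with EGF-like domains, rose 2.69-fold (log2 1.43, SE 0.21, limma adjusted p = 0.0484; well above background on 3 of 3 arrays with salt and 1 of 3 without). Its adjusted p was 0.121 and 0.17 without knockout infusion arrays 1 and 2, and 0.305, 0.281 and 0.191 without arrays 1, 2 and 3 of the knockout with salt and infusion. The count was 0 in those fits, after quantile normalisation or normexp correction and with slide as a random block, 92 without knockout infusion array 3, 271 with slide as a block and 0 within slide 2. The difference for Scube1 between genotypes was 1.82 (SE 0.30, adjusted p = 0.19). Mesothelial and epithelial markers fell by a median of −1.73 over 11 genes, with 0 past over all genes and 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 1.63e-14; adjusted p = 0.381 with an estimated correlation). The keratins Krt8 and Krt14 had log2 −1.85 (SE 0.60) and −0.97 (SE 0.25). The median was −1.52 with slide as a block (adjusted p = 0.0135), −1.52 within slide 2 (adjusted p = 0.105) and −0.73 without array 2 of the knockout with salt and infusion (adjusted p = 1.62e-06).

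The IL-17 response list had a median of −0.27 with salt under infusion in the knockout (camera adjusted p = 0.00926; adjusted p = 0.976 with an estimated correlation), with no member past either adjustment. It was −0.22 with slide as a block (adjusted p = 0.896), not past within slide 2 (adjusted p = 0.706), −0.06 without knockout infusion array 1 (adjusted p = 0.666) and −0.24 without array 1 of the knockout with salt and infusion (adjusted p = 0.0858). The neutrophil proteins S100a9 and S100a8 had log2 −2.11 (SE 1.27) and −2.05 (SE 1.28). Immediate early genes fell by a median of −0.45 over 22 genes (camera adjusted p = 5.39e-06; adjusted p = 0.84 with an estimated correlation), by −0.18 without knockout infusion array 3 (adjusted p = 0.303), and by −0.91 with the slide block, which rests on that array alone as the group without salt. Fibroblast markers fell by a median of −0.33 (camera adjusted p = 3.87e-06; adjusted p = 0.544 with an estimated correlation), −0.38 with the slide block (adjusted p = 0.0444).

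Whether salt under infusion acted differently in the knockout was tested as the difference of the 2 changes, and 0 genes passed (limma, smallest adjusted p 0.19; 1641 at an unadjusted p under 0.05), with 42 under the slide block, 33 without knockout infusion array 3 and 7 without array 3 of the wild type with salt and infusion. The 2 sets of log2 changes had Pearson's r of −0.116 across genes. Between genotypes the IL-17 response list differed by −0.18 (camera adjusted p = 0.778), by −0.21 with the slide block, by 0.05 without knockout infusion array 1 and by 0.03 without array 3 of the wild type with salt and infusion. It passed in both directions when 1 array was left out, at −0.49 without wild-type infusion array 2 (adjusted p = 0.00611) and 0.46 without wild-type infusion array 3 (adjusted p = 0.00595). Mesothelial markers differed by −2.45 (−1.73 in the knockout and 0.70 in the wild type; camera adjusted p = 1.49e-10; adjusted p = 0.86 with an estimated correlation), by −1.55 with the slide block (adjusted p = 0.0682) and by −1.38 without array 2 of the knockout with salt and infusion. Immediate early genes differed by −0.68 (camera adjusted p = 1.67e-07; adjusted p = 0.86 with an estimated correlation), by −1.87 with the slide block, by −0.26 without the third infusion-only arrays (adjusted p = 0.0492) and by −0.33 without array 3 of the wild type with salt and infusion. Unfolded protein response genes differed by −0.28 (0.01 and 0.32; camera adjusted p = 0.000203; adjusted p = 0.86 with an estimated correlation). Their difference was −0.65 with the slide block, −0.0652 without the third infusion-only arrays (adjusted p = 0.132), −0.14 without array 1 and −0.47 without array 3 of the knockout with salt and infusion, −0.13 without wild-type infusion array 3 and −0.43 without array 1 of the wild type with salt and infusion.

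**Figure D4:**
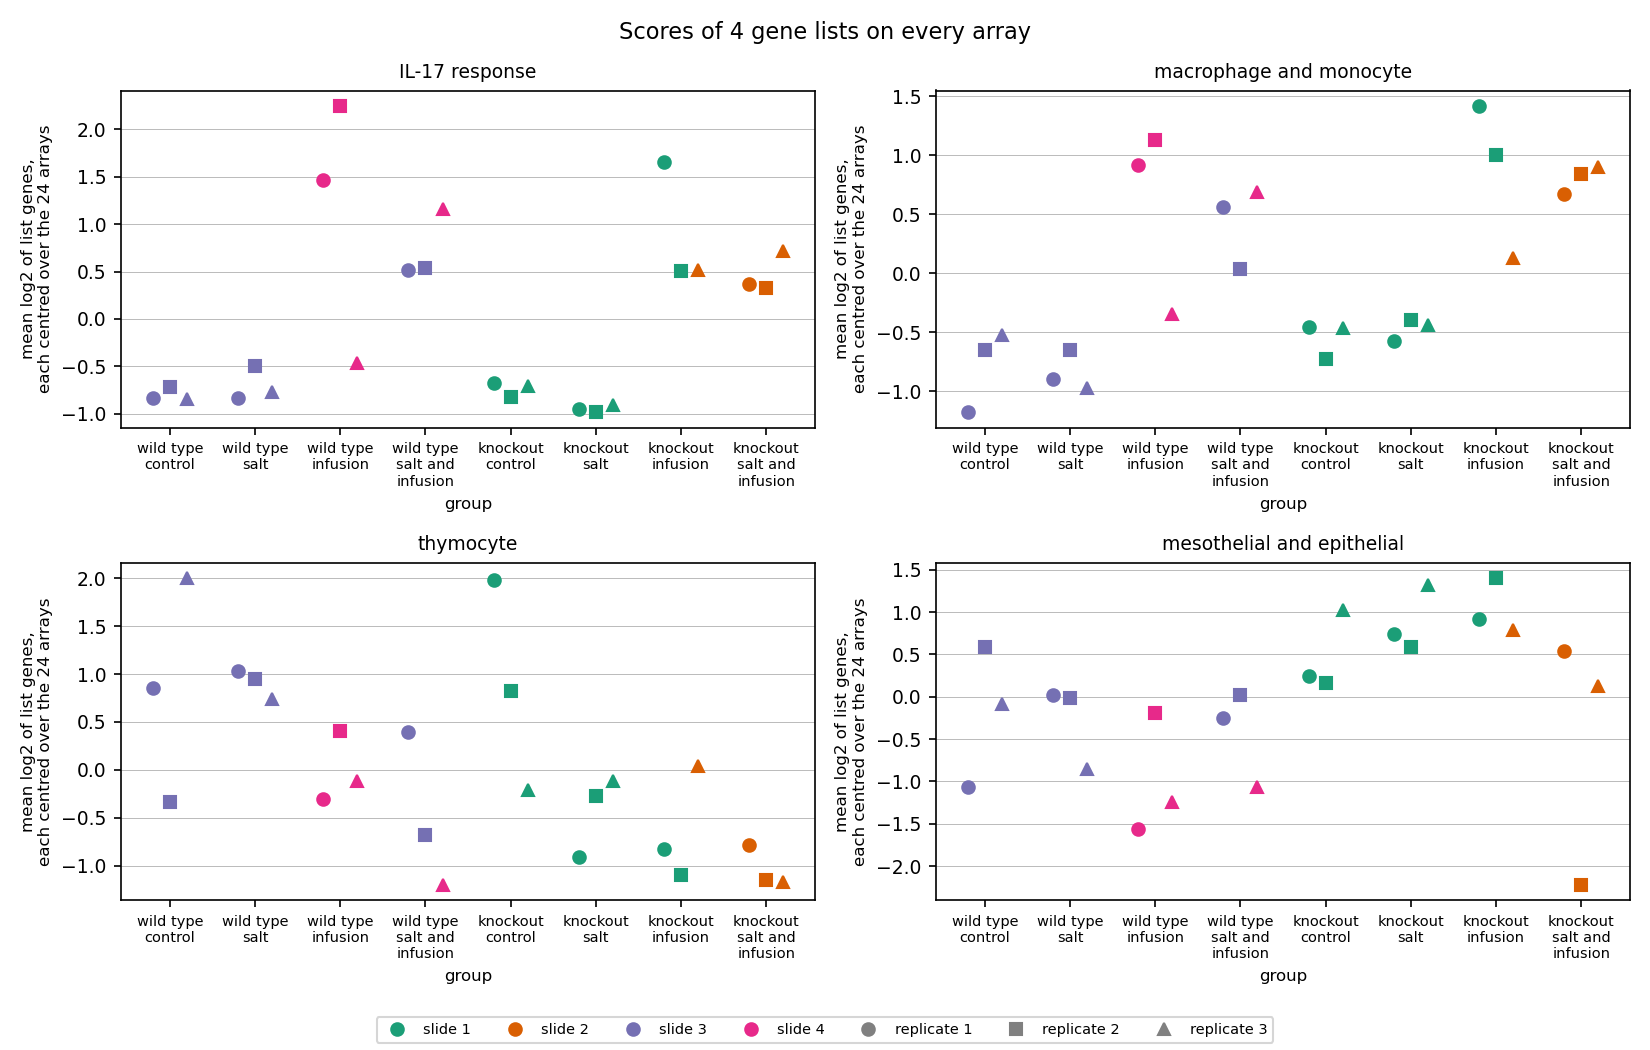
Score of gene lists on each of the 24 arrays, as the mean log2 signal of the list's genes after centring each gene over all arrays; colours are slides and marker shapes replicate numbers. IL-17 response scores of the infused wild type on plain water are 1.47, 2.25 and −0.465, and those with salt 0.516, 0.54 and 1.16.

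The genotypes were compared in vehicle controls and under salt with infusion. Slide and genotype cannot be told apart in either. In controls 8737 genes passed, 3392 higher and 5345 lower in the knockout (limma, adjusted p under 0.05), and after quantile normalisation 4312 were higher and 4172 lower. A random slide block left 1984. Raly, which encodes an RNA-binding protein, was 22.2-fold higher in the knockout (log2 4.47, SE 0.21, adjusted p = 1.3e-10) and Tnxb, the matrix protein tenascin X, 24.2-fold (log2 4.60, SE 0.38, adjusted p = 7.48e-08). Dpt, the matrix protein dermatopontin, was 9.33-fold higher. Nwd2 was at least 9.58-fold lower.

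Fibroblast markers were higher in the knockout controls, with a median of 0.55 and 7 of 19 higher and 0 lower under either adjustment (camera adjusted p = 0.00271; adjusted p = 0.684 with an estimated correlation). Fatty acid oxidation and lipid synthesis genes, a list of opposed pathways, had a median of 0.37, with 13 of 26 higher and 1 lower under either adjustment (camera adjusted p = 0.00525; adjusted p = 0.488 with an estimated correlation). Complement and coagulation genes had a median of 0.49, with 8 of 27 higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0172, or 0.0768 without wild-type control array 1; adjusted p = 0.677 with an estimated correlation). C3, the central complement component, was higher by 1.13 (SE 0.22) and Cfb by 1.02 (SE 0.15).

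Under salt with infusion 6711 genes differed between genotypes, 2468 higher and 4243 lower in the knockout, or 2839 and 3133 after quantile normalisation. The count was 4113 without array 1 of the knockout with salt and infusion, 11798 under normexp correction and 2361 with slide as a random block. Tnxb was 15.2-fold higher (log2 3.93, SE 0.38), Raly 11.8-fold and Dpt 8.10-fold. Between the 2 genotype comparisons 1774 genes were higher in both against 356 by chance, 3467 lower in both against 965, and r was 0.866 across genes. Interferon response genes were higher in the knockout, with a median of 0.88 and 12 of 26 higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 0.000129; adjusted p = 0.938 with an estimated correlation). Isg15 was 4.69-fold higher (log2 2.23, SE 0.38, adjusted p = 0.000315) and Oas2 2.98-fold. Fibroblast markers had a median of 0.63 with 6 of 19 higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.000359; adjusted p = 0.808 with an estimated correlation).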

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

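The test of intensity spread behind the genotype calls and the test for a mislabelled infusion array were chosen after their results were seen, as was leaving out the third infusion-only arrays.

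Between the genotypes 8737 genes passed in controls, and no slide held both, so a slide or scan effect cannot be told from the genotype. A different spread of intensities on the 2 sets of slides is argued against as the whole source. After quantile normalisation 6733 of the 8737 passed in the same direction (8484 in all). Spearman's rho of the change with mean level over genes fell from 0.348 to 0.0597. Probe base composition is argued against likewise. After each array's trend over probe GC was taken out 8870 genes passed, 6983 in both fits with the same direction. Genes changed at least 2-fold were more frequent within 10 Mb of Il17a, 21 of 73 against 3581 of 23261 elsewhere. Two-sided Fisher's exact p was 0.0032 (odds ratio 2.22, confidence interval 1.27 to 3.75). DNA of another strain there could give this if Il17a is deleted, which the labels do not say. Most of the 21, many with only a database name, were lower in the knockout, as over all genes (2-fold calls 3278 lower, 368 higher). Not all 21 passed under salt with infusion. The test was not redone after quantile normalisation, so intensity spread stays open there. Neighbouring probes are not independent, and the genotype stays open.

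Wild-type infusion array 3 lay at 0.531 on the wild-type scale from controls to salt with infusion, where uninfused arrays reached 0.114 and the other infused arrays started at 0.711. That position lies above the limit of 0.289 set by the uninfused arrays, which argues against a mislabelled uninfused sample. A plain mixture of infused and uninfused RNA would lower every list to one share of a common infused level. Cell cycle genes stood at 49.5%, and 6 macrophage, 13 inflammatory, and 3 collagen and fibrillar matrix genes at 16.1%, 18.8% and 18.1%. The lower quartile of cell cycle genes, 43.9%, lay 16.9 points above the upper quartile of the 6 macrophage genes and above that of the 13 inflammatory genes, 31.6%. A weaker or later response in that mouse may remain, and no biological explanation was tested.

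T and NK cell markers (−0.74) and thymocyte markers (−1.04) differed between genotypes in their change with salt, but not with an estimated correlation (adjusted p = 0.854 and 0.751), without knockout control array 1 (0.0595 for both) or without wild-type control array 2 (0.154 and 0.0595). The thymocyte scores of the 3 knockout controls were 1.98, 0.818 and −0.207. Their range, 2.18 on the log2 scale, exceeded the 1.30 between controls and salt, as lymphoid tissue carried along in some control aortas could give. Brown and white adipocyte markers moved alike there (−0.19 and −0.21). In the wild type brown ones fell too (−0.26, camera adjusted p = 0.0275) and thymocyte markers did not (0.07). That fall passed in 3 of 6 fits that leave out an array. An effect of salt on T cells stays open.

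For salt with infusion the genotype difference passed for Stard3 (1.13), Gm9706 (2.30), Vmn1r139 (1.63) and 3 database-named transcripts (3.25, 1.82 and 2.66). Vmn1r139, well above background on 5 of 24 arrays, has no measured fold. Mesothelial markers with salt under infusion in the knockout had a median of −1.52 with slide as a block. Their score changed by −1.55, with an SD of 0.446 among uninfused knockout arrays, and array 2 of the 3 with salt was lowest (0.547, −2.22 and 0.128), with a list median of −0.73 that still passed without it (adjusted p = 1.62e-06).

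The response to infusion differed between genotypes for 6 lists, none with an estimated correlation. Here fits are those that leave out an array, and combined arrays those with salt and infusion. Interferon response genes (0.81) and mesothelial markers (1.46) passed in 12 of 12 fits, at lowest 0.50 and 0.95 without wild-type infusion arrays 3 and 1, and had 0.40 and 0.38 with the slide block, where neither passed. Fibroblast markers (0.32) passed in 4 of 12 and turned to −0.0728 with the slide block. They did not pass without knockout control array 1 or 2, knockout infusion array 2 or 3 (0.24 and 0.15), wild-type control array 2 or 3, or wild-type infusion array 1 or 2 (0.0914 and 0.30), and had 0.51 without knockout infusion array 1. Matrix proteases (−0.28, −0.12 with the slide block) did not pass without knockout control array 3, knockout infusion array 3, wild-type control array 1 or 3, or wild-type infusion array 1 or 2 (−0.10 without the latter), and had −0.48 without wild-type infusion array 3. Unfolded protein genes (0.21, 0.54 with the slide block) did not pass without knockout control array 2, knockout infusion array 1 or 3 (0.11 without the latter), wild-type control array 1 or 2 (0.13 without the latter), wild-type infusion array 3 (0.0448) or the third infusion-only arrays (0.0137). Oxidative phosphorylation genes (0.15, 0.58 with the slide block) did not pass without knockout infusion array 2 (0.0621) or wild-type infusion array 3 (0.0265), and had 0.25 and 0.27 without knockout infusion array 3 and wild-type infusion array 1.

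For salt with infusion 7 lists differed, none with an estimated correlation. Interferon response genes (0.62, 1.04 with the slide block) did not pass without wild-type combined array 3 (0.45). Matrix proteases (−0.25) passed in 12 of 12 fits and not with the slide block (−0.0620). Endothelial markers (−0.24) turned to 0.69 with the slide block and passed there too (adjusted p = 0.0168), and did not pass without wild-type combined array 3 (adjusted p = 0.0556), with −0.49 without knockout combined array 1. Immediate early genes (−0.37, −1.12 with the slide block) had −0.58 and −0.20 without wild-type combined arrays 2 and 3, not passing in the latter. Mesothelial markers (−0.81, adjusted p = 0.697 with the slide block and 0.059 without the third infusion-only arrays) had 0.0517 without knockout combined array 2 (adjusted p = 0.971), did not pass without knockout control array 3 (−0.55), wild-type control array 1 (−0.44) or wild-type combined array 2 (−0.57), and had −1.47 and −1.24 without knockout combined array 1 and wild-type control array 2. TGF-beta response (−0.18) and osmotic response genes (−0.22) each passed in 6 of 12 fits and not with the slide block. Neither passed without knockout control array 2 or 3, knockout combined array 1 (−0.11 and −0.20), wild-type control array 3 (−0.0969 and −0.16) or wild-type combined array 2 (−0.10 and −0.25). The TGF-beta list also did not pass without knockout combined array 2 and had −0.30 without array 3 of that group, and the osmotic list had −0.13 without wild-type combined array 3, not passing, and −0.33 without array 1.

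For salt under infusion 6 lists differed, none with an estimated correlation. Mesothelial markers (−2.45), immediate early (−0.68), unfolded protein response (−0.28) and oxidative phosphorylation genes (−0.24) passed in 12 of 12 fits, the first not with the slide block (adjusted p = 0.0682) and the unfolded protein genes not without the third infusion-only arrays (−0.0652, adjusted p = 0.132), and the last had −0.12 and −0.14 without wild-type infusion array 3 and wild-type combined array 3. Contractile genes (−0.23, −0.59 with the slide block, and −0.0324 without the third infusion-only arrays, not passing) had 0.0368 without knockout infusion array 3 (adjusted p = 0.779), and did not pass without knockout combined array 1 (−0.0787), wild-type infusion array 1 or 2 (−0.19 and −0.14) or wild-type combined array 2 (−0.0538). Fibroblast markers (−0.28, adjusted p = 0.713 with the slide block) passed in 5 of 12. They did not pass without knockout infusion array 2 or 3 (−0.31 and −0.0953), knockout combined array 3, wild-type infusion array 1 or 2, or wild-type combined arrays 1 or 2 (−0.26 and −0.17).

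Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most genes, as the 1 split of 10 with as many, for infusion in the wild type (6086, highest other 19) and the knockout (7202, 29), salt with infusion in the wild type (6748, 2) and the knockout (6034, 0), and genotype in controls (8737, 0) and under salt with infusion (6711, 0), and for the IL-17 response median with salt and infusion in the wild type (1.04, −0.61). Where the real count is 0, as for salt alone in both genotypes (highest other 0 and 3) and salt under infusion in the wild type (highest other 812), 10 of 10 splits give as many by construction, which says nothing about chance. For salt under infusion in the knockout 2 of 10 splits gave as many (1, highest other 2144), and in the wild type 7 of 10 gave an IL-17 response median as far from 0 (−0.20, highest other −1.25). The split with 812 genes set wild-type infusion array 3 with arrays 1 and 2 of the salt group, and that with 2144 set knockout infusion arrays 1 and 2, the 2 on slide 1, with array 1 of the salt group, which points to a structure of the samples.

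For the differences between genotypes 100 splits were drawn. For salt with infusion 8 gave as many genes (6, highest other 3463). An IL-17 response median as far from 0 came in 87 (−0.13, 1.41), and in 75 for salt under infusion (−0.18, −1.90). For salt, infusion and salt under infusion the real count was 0 (highest other 1, 5915 and 4067), so all gave as many by construction. No share decides on chance. Splits that mix infused and vehicle arrays can carry the infusion effect (5915 and 3463), and 4067 points to sample structure.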

How the results depend on the processing

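Leaving out the third infusion-only arrays was chosen after seeing the data, and where a result changed the cause was not tested.

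Signal over background limits the dim genes. A gene dim in a whole group has only a bound, and Il17a and Il17f have no fold. With only genes well above background on all 24 arrays, salt in the wild type gave 1 gene, salt under infusion in the knockout 0 and the genotype difference of salt with infusion 13. With no filter, salt under infusion in the wild type gave 4 genes, the genotype difference of infusion 1, and the IL-17 response median for salt under infusion in the wild type was −0.22 and passed.

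Quantile normalisation and the authors' processed values each gave 0 genes for salt under infusion in the knockout and 12 for the genotype difference of salt with infusion. Normexp correction gave 0 for salt under infusion in the knockout, 11798 for genotype under salt with infusion, and −0.14 for the IL-17 response list with salt under infusion in the wild type, which passed. Under it these changed sign with salt under infusion in the wild type: Vmn1r139 0.0482, Ptcra 0.0273 and Scnn1a 0.0738. So did Vmn1r139 −0.0671, Krt14 −0.0913 and Scnn1a −0.00974 in the genotype difference of salt with infusion, and Mmp9 −0.13 in that of salt under infusion. With the mean of a gene's probes Atp5g1 was −0.0278 for infusion in the knockout. A prior variance with a trend gave 1 gene for salt in the wild type and 0 for salt under infusion in the knockout.

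Slide as a fixed block gave 2 genes for salt in the wild type, 261 for infusion and 9 for salt under infusion in the wild type, 271 for salt under infusion in the knockout, and 46, 1380 and 42 for the genotype differences of infusion, salt with infusion and salt under infusion. Signs turned for Plin4 (0.0493) with infusion in the wild type, for Gbp3 (−0.14), Elane (0.0818), Muc16 (−0.31) and the IL-17 response list (0.0926) with salt under infusion in the wild type, for Cxcl5 (0.56) and Pi16 (−0.19) in the genotype difference of infusion, and for Zc3h12a (−0.0859), Ptprb (0.0533) and Sox17 (0.67) in that of salt with infusion. The arrays of slide 4 alone gave the same values for Gbp3 (−0.14), Elane (0.0818) and Muc16 (−0.31), and those of slide 2 alone gave 0 genes for salt under infusion in the knockout. Each of these slides held 1 array of one of the groups, which was taken to vary like the others. A random slide block gave 3 genes for salt and 770 for infusion in the wild type, 0 for salt under infusion in the knockout, 1984 and 2361 for genotype in controls and under salt with infusion, 12 for the genotype difference of salt with infusion, Sox17 0.0647 there and the IL-17 response list 0.0235.

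Same-numbered arrays did not deviate together (mean r −0.0173 over 84 pairs, 13 over 0.1; 0.00898 over 168 pairs of different number), and 4 of 24 arrays lay closest to their own number, so the numbers do not pair the samples. The replicate block gave 0 genes for salt under infusion in the knockout and moved no other count by over 1.5 times.

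With only the compared groups in the fit, infusion gave 1237 genes in the wild type and 2390 in the knockout, salt under infusion 0 in the knockout, the genotype difference of salt with infusion 24, and its IL-17 response median of −0.13 passed. With an estimated correlation the IL-17 response median of 1.04 for salt with infusion in the wild type did not pass. Without the third infusion-only arrays infusion in the wild type gave 9405 genes, salt under infusion 2 in the wild type and 393 in the knockout, and the genotype differences of infusion and salt under infusion 43 and 4. Xbp1 was then −0.0444 and Edem1 −0.0132 in the genotype difference of infusion, and the IL-17 response list −0.77 with salt under infusion in the wild type and 0.46 in its genotype difference.

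With 1 array left out, which leaves 2 in a group, counts ran from 0 to 1 for salt, 2674 to 8105 for infusion, 3917 to 7403 for salt with infusion and 0 to 16 for salt under infusion in the wild type. In the knockout they ran from 0 to 2, 3964 to 9739, 3849 to 5114 and 0 to 92. Genotype gave 6343 to 8235 in controls and 4113 to 6815 under salt with infusion, and the genotype differences 0 to 0 for salt, 0 to 63 for infusion, 0 to 10 for salt with infusion and 0 to 33 for salt under infusion. The IL-17 response median ran from 0.71 to 1.21 for salt with infusion and −0.77 to 0.11 for salt under infusion in the wild type, and from −0.36 to 0.0648 and −0.49 to 0.46 in the genotype differences. Upk3b ran from −1.89 to 0.0200 in the genotype difference of salt with infusion, turning without array 2 of the knockout. Values of named genes kept direction and side of the threshold in 4704 of these fits, no longer passed in 146, newly passed in 21 and turned in 1. The counts were 679, 5, 0 and 0 for quantile normalisation, 657, 18, 2 and 7 for normexp correction, 514, 66, 10 and 9 for the fixed and 617, 65, 1 and 1 for the random slide block.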

Other observations

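The average of salt over the 4 backgrounds was chosen after the files had been read.

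Some gene groups moved that the comparisons above left out. Skeletal and cardiac muscle genes fell in the knockout with salt and infusion, by a median of −0.91 with 0 of 19 higher and 6 lower (1 and 8 adjusted over the list alone; camera adjusted p = 0.0103, or 0.0644 without array 2 of that group; adjusted p = 0.496 with an estimated correlation). Brown adipocyte genes fell in the infused knockout, by a median of −0.69 with 1 of 19 higher and 6 lower (1 and 10 adjusted over the list alone; camera adjusted p = 0.00945; adjusted p = 0.484 with an estimated correlation). JAK-STAT3 and acute phase genes rose there by a median of 1.26, with 11 of 22 higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.00851; adjusted p = 0.484 with an estimated correlation). The receptor subunits Il6st and Lifr, through which cytokines of the IL-6 family signal, changed the other way, by −0.61 and −0.88.

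Averaged over genotype and infusion, 12 arrays with salt against 12 without gave 0 genes (limma, smallest adjusted p 0.0876; 623 at an unadjusted p under 0.05), so that 100 of 100 splits that swap salt within each background gave as many by construction (highest other 2), which says nothing about chance. Thymocyte markers had a median of −0.67 (camera adjusted p = 5.29e-07; adjusted p = 0.377 with an estimated correlation), platelet markers 0.19 (adjusted p = 0.000762; adjusted p = 0.377 with an estimated correlation) and unfolded protein response genes 0.07 (adjusted p = 0.000168; adjusted p = 0.604 with an estimated correlation). The IL-17 response list had a median of −0.01 (adjusted p = 0.0587).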
